A study of Rattus norvegicus with 6 samples.

How the data were processed

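Gene expression was measured in renal cortex of male Sprague-Dawley rats with 1-colour Agilent microarrays, on which each RNA is labelled with the dye Cy3 and hybridised to oligonucleotide probes. The 6 arrays fall into 2 groups of 3: rats given corn oil, the vehicle, and rats given monuron at 200 mg/kg/day, both for 4 weeks. Groups, doses and replicate numbers come from the labels, and the design text speaks of 3 biological replicates per group. All 3 corn oil arrays lay on a slide of their own and all 3 monuron arrays on another, scanned on different days, per the file headers. Of the 2 slides, 0 held both groups, so slide, scan day and treatment cannot be told apart.

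The deposited scanner files hold the spot intensity on a linear scale, extracted by the authors with Agilent Feature Extraction 10.7, per the submitters' processing notes. The processed signal, the median spot signal and the local background were used as given. The authors' deposited value table holds a linear ratio. Set against the scanner files, its values of at least 0.1 equal the probe's mean processed signal divided by 1 constant per array within 0.0497%, with a 75th percentile of 1 in each column after rounding, so its scale and scaling are settled from the values. Its column medians were 0.108, 0.111 and 0.112 for corn oil replicates 1 to 3 and 0.111, 0.111 and 0.110 for monuron replicates 1 to 3.

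The main values were log2 of the processed signal minus the array's 75th percentile over the 61537 non-control probes. The 1439 control spots and spots marked as feature outliers were left out, and saturated spots would have been kept, of which there were 0. A probe was kept where it was well above background on all 3 arrays of at least 1 group, which left 41125 probes. The plan had counted on a column of gene names and on the mean spot signal, and the scanner files hold neither: they name probes by accession, and the median spot signal took the place of the mean. The accessions, without versions, were matched to a RefSeq gene table (assembly GRCr8), which named 28206 probes (45.8%) and 15645 distinct symbols. The other probes kept the file's accession or probe ID, and gene symbols reported here rest on that match alone. The array design cites an older rat build, so no coordinates are given. For each gene name the probe with the highest mean over the 6 arrays was tested, which gave 30229 genes, 12057 of them with a symbol. For some genes with several passing probes the range over them is given.

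Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment over all genes, threshold 0.05). All adjusted p-values for genes are from this test, errors of log2 fold changes are standard errors, and errors of levels are SD over n = 3 arrays. Gene lists were compared with limma's camera at a preset inter-gene correlation of 0.01, for lists with at least 5 measured members, adjusted over all 51 lists. Camera with an estimated correlation and fry, which asks whether a list's genes move one way on balance, were run beside it. Genes not well above background on any array of a group are given as bounds: the other group's mean against the mean, over the dim group's arrays, of the lowest signal well above background or the probe's own signal if higher. The functions were tested on simulated arrays of 30208 genes built from the real means and residual spread of the monuron against corn oil comparison. In 5 runs with 200 changed genes each, 34.9% of genes changed 1.5-fold, 66.9% of those changed 2-fold and 86.4% of those changed 4-fold were called, 33 of 664 calls were false, and a list raised by 0.5 on the log2 scale was called in all 5 runs with 0 calls among the 50 other lists. The genes were simulated independently of each other. The runs therefore do not show how often lists of correlated genes are falsely called at the preset correlation.

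Before the data were examined, the following was fixed: the groups, the main settings, 51 lists of pathway genes and cell type markers, the alternatives, and the rule for named genes. The rule took the 12 largest rises and 12 largest falls among called genes with a symbol whose groups did not overlap, up to 4 members of each list with the smallest p, and 18 genes in every case. Not every gene of the rule is named. Named here are called genes of the rule, the genes named in every case, and a few uncalled list members picked from the rule's genes after their values were seen. Of the 18, Cyp1a1 and Cyp2b1 had probes below the detection filter and Top2a had no probe named for it. Alternatives were quantile normalization, median centring, no scaling, normexp background correction (offset 50, on the median spot signal) with quantile normalization, the authors' table, no detection filter, detection on all 6 arrays, a floor on low values, the mean of a gene's probes, every probe on its own, eBayes with trend and robust, array weights, the replicate number as a block, and leaving out each array. A slide block was not possible. Added after seeing the data were scaling on spike-in controls, leaving out 2 arrays together, and a covariate for liver transcripts. The number of arrays limits the precision of every value.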

Results

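Renal cortex of rats dosed for 4 weeks with monuron, a phenylurea herbicide, was compared with that of rats given corn oil, 3 arrays per group. Between 60.9% and 70.4% of the non-control probes were well above background on each array, with the fewest on corn oil replicate 2 (37454 probes) and the most on monuron replicate 1 (43349). The 75th percentile of the signal lay between 825 and 922 units. The first principal component, with 37.0% of the variance, separated the groups, and the second (21.9%) spread the corn oil arrays. The comparison asks which transcripts differ in the cortex after repeated dosing with the herbicide.

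Tested as lists at a preset correlation, transcripts of tubule injury, cell division, oxidative stress defence and red cells were higher in monuron-dosed cortex. Fatty acid oxidation, proximal tubule segment S1 and S2 and interferon response transcripts were among the lower lists. With an estimated correlation 0 of the 51 lists passed, with 12 at an unadjusted p under 0.05. The adjusted p was then 0.0855 for injury, 0.0954 for mitosis, 0.0687 for NRF2 targets and 0.127 for erythroid genes. It was 0.0933 for fatty acid oxidation, 0.109 for S1 and S2 and 0.336 for interferon response genes. Of these 3 lower lists fry called fatty acid oxidation (adjusted p = 0.0102) and S1 and S2 (0.0120), each with 0 members called over all genes. It did not call interferon response (0.0540). The largest rise among called genes with a symbol was that of Havcr1, which encodes kidney injury molecule 1, a transmembrane protein of damaged proximal tubule. It was 13.4-fold higher (95% interval 9.51 to 19.0, adjusted p = 0.00623) and was well above background on 2 of the 3 corn oil arrays. In all, 287 genes were higher and 125 lower with monuron out of 30229 tested, and 150 and 41 of these differed at least 2-fold. Of the 412 called genes, 200 had a symbol. The groups did not overlap in 25.7% of all tested genes, where chance gives 10%. An unadjusted p under 0.05 was reached by 5320 genes, 3285 of them higher.

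After Havcr1, the largest rises were those of Alox15, a lipoxygenase (9.57-fold), Vxn (6.21-fold), Mogat2, an acyltransferase of triglyceride synthesis (5.62-fold), and Areg, a ligand of the epidermal growth factor receptor (5.60-fold). Gtse1, which is expressed in the later cell cycle, ranked among them on its measured values, but its place is not settled. Gtse1 was not well above background on any corn oil array and was at least 2.88-fold higher. It was called on its measured values (adjusted p = 0.0124) but not with low values set to a floor (adjusted p = 0.101, with a range of 0.0031 to 0.142 over the alternatives). Next came Nqo1, a quinone reductase (5.33-fold), the efflux pump gene Abcb1b (5.25-fold), Csmd1 (5.07-fold, well above background on 1 of 3 corn oil arrays), Pipox, an oxidase of sarcosine and pipecolate (5.04-fold), Ckap2, a spindle protein (4.79-fold), and the organic anion efflux pump gene Abcc2 (4.49-fold, 95% interval 3.90 to 5.16, adjusted p = 0.00387). The 3 probes of Mogat2 differed, with log2 fold changes from 0.39 to 2.49, and those of Abcb1b ranged from 2.28 to 4.36. Named after their values were seen, the probes without a symbol that changed most were C_CA_A0016, which rose by 4.73 ± 0.33 on the log2 scale, and the EST DV726161, at least 4.44-fold lower and not well above background with monuron.

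Among the largest falls were those of Gabbr2, a subunit of the GABA-B receptor (6.80-fold lower, log2 fold change -2.77 ± 0.32), and Cish, a suppressor of cytokine signalling (4.75-fold lower, -2.25 ± 0.18). Tex26 fell 3.34-fold, the methyltransferase gene Inmt 3.27-fold, Sugct 2.93-fold (probes from -1.55 to -0.84 on the log2 scale), Fhit 2.78-fold, the receptor kinase gene Ror1 2.70-fold and Usp18, a protease that removes ISG15, 2.64-fold. Slit3, Prima1 and Zpbp were between 2.23-fold and 2.25-fold lower. A further probe of Prima1 showed no such fall, with a log2 fold change of -0.06, and the mean of its probes was not called (adjusted p = 0.0669, 0.0031 to 0.23 over the alternatives). The arrays of both groups are drawn for 12 of the named genes.

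**Figure D1:**
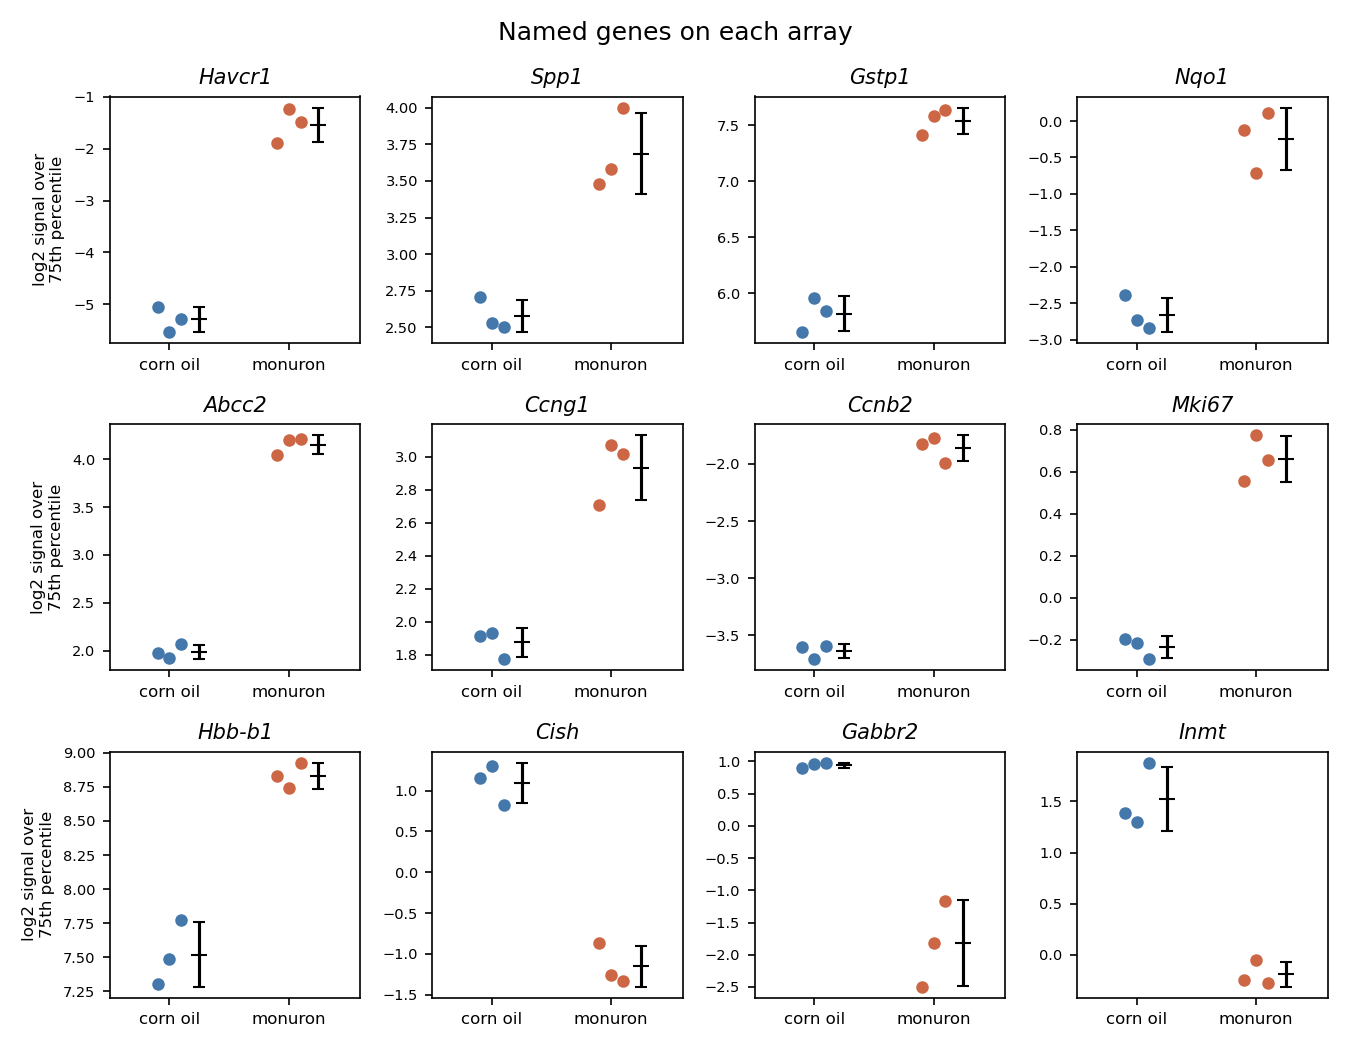
Level of 12 named genes on each array, as log2 signal over the array's 75th percentile (y axis, scaled per gene), for 3 corn oil and 3 monuron arrays (points), with mean and SD beside them. For each gene the groups do not overlap, and Havcr1 lies at -5.29 ± 0.24 with corn oil and -1.54 ± 0.33 with monuron (SD, n = 3).

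Each group lay on a slide of its own, so group and slide cannot be told apart in any value. Leaving out a single array lowered the genes higher and lower to 97 and 17, 81 and 19, and 1.1e+02 (rounded) and 27 without corn oil replicates 1 to 3 in turn, and to 25 and 5, 52 and 10, and 28 and 7 without monuron replicates 1 to 3. Without a detection filter 67 and 19 genes were called, and of the 53 called genes named here 5 (Havcr1, Ckap2, Abcc2, Gstp1 and Ccnb2) kept their call without each array in turn. All changes are relative to each array's 75th percentile: without scaling the median log2 fold change of all genes was 0.11 in place of 0.02, and scaled on spike-in controls it was -0.48, with 303 genes called higher and 20640 lower. That scaling shifted every gene by about -0.50, and the medians of the NRF2 (-0.14), DNA replication (-0.15), p53 (-0.23), glutathione transferase (-0.29) and cholesterol synthesis (-0.31) lists, called higher relative to other genes, then lay below 0. With a score of hepatocyte transcripts as a covariate limma called 96 genes higher and 16 lower, and without the pair of arrays highest in liver transcripts it called 0 and 0, with 4190 at an unadjusted p under 0.05. The calls were lost there, while sizes of named genes changed less. For example, the log2 fold change was 3.93 for Havcr1 (3.75 with all arrays), 2.26 for Abcc2 (2.17) and -2.42 for Gabbr2 (-2.77).

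Genes of cell division formed the list with the largest median, while the mean was larger for AhR targets (1.48) and erythroid markers (1.31) than for mitosis genes (1.20). Of 32 measured mitosis genes 19 rose, 0 fell, and all 32 had a log2 fold change above 0 with a median of 1.32. Adjusted over the list alone, 30 rose. Ccnb2, a mitotic cyclin, was 3.41-fold higher (2.96 to 3.94, adjusted p = 0.00486), the kinesin gene Kif20a 2.99-fold, the spindle midzone gene Prc1 2.72-fold (probes from 1.44 to 2.07 on the log2 scale) and the mitotic kinase gene Plk1 2.70-fold. The proliferation marker Mki67 was 1.86-fold higher, and its 5 probes had log2 fold changes from 0.90 to 1.35. Of 33 DNA replication genes 5 rose and 0 fell (median 0.36), and 12 rose adjusted over the list alone. Among them Rrm2, a subunit of ribonucleotide reductase, was 3.22-fold higher, E2f1 1.88-fold, Mcm6, a helicase subunit, 1.68-fold and Cdc45 1.41-fold, the last by a log2 of 0.49 that spike-in scaling brings to -0.010. Camera gave adjusted p = 2.53e-29 for mitosis and 8.37e-08 for replication. With an estimated correlation these were adjusted p = 0.0954 and adjusted p = 0.0687. Red cell transcripts were higher with monuron as well, though their order over the monuron arrays was not that of the mitosis genes. Of 11 erythroid cell markers 4 rose and 0 fell, and the median was 1.31, or 0.98 with dim genes at their bound.

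The erythroid genes that rose were Alas2, the heme synthesis enzyme of red cell precursors (3.73-fold, adjusted p = 0.0111), the beta globins Hbb-b1 (2.48-fold) and Hbb (1.97-fold), and the transcription factor gene Klf1 (1.87-fold). Adjusted over the list alone 10 of 11 rose. The list's camera adjusted p was 1.01e-09, and adjusted p = 0.127 with an estimated correlation. A second probe of Klf1 had a log2 fold change of 0.16. Without monuron replicate 1 that probe was the brighter and not called (0.25, adjusted p = 0.576, with a range of 0.0155 to 0.576 over the alternatives), and the first probe stood at 0.85.

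Of 25 kidney tubule injury genes 4 rose and 0 fell (median 0.55), and 7 rose adjusted over the list alone (camera adjusted p = 4.44e-06, and adjusted p = 0.0855 with an estimated correlation). Besides Havcr1 these were the stress cytokine gene Gdf15 (2.70-fold), the osteopontin gene Spp1 (2.15-fold) and the keratin gene Krt8 (1.46-fold, adjusted p = 0.0495, with a range of 0.0158 to 0.692 over the alternatives and the call lost in 18 of 22). Lcn2, another injury marker, had a log2 fold change of 0.62 ± 0.26 and Clu of 0.01 ± 0.42, and neither was called.

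Of 22 p53 target genes 4 rose and 0 fell (median 0.27), and 7 rose adjusted over the list alone (camera adjusted p = 4.18e-05, and adjusted p = 0.0933 with an estimated correlation). They were Plk2 (3.17-fold), Ccng1, cyclin G1 (2.08-fold), Psrc1 (1.79-fold) and the death receptor gene Fas (1.66-fold). Psrc1 is also a spindle protein. The probes of Ccng1 ran from 1.06 to 2.06 on the log2 scale, and with the mean of a gene's probes neither Ccng1 (adjusted p = 0.0979, 0.00476 to 0.139 over the alternatives) nor Fas (0.0694, 0.0107 to 0.189) was called. Mdm2 had a log2 fold change of 0.30 ± 0.08 (adjusted p = 0.151). The probes of Cdkn1a, the p21 gene, disagreed: the brightest gave 0.15 ± 0.07 and was not called, whereas the dimmer probes gave 2.04 ± 0.17 and 2.32 ± 0.24, and the mean of the 3 probes gave 1.5 ± 0.12 with adjusted p = 0.011. Scaled on spike-in controls the brightest probe stood at -0.35.

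Some lists of stress defence and drug metabolism genes were also called higher at the preset correlation. Several of them share members, so their calls are not independent. The NRF2 and glutathione transferase lists share 6 genes, Gstp1 and Gstm1 among them. Nqo1 is in both the NRF2 and AhR lists, and Ephx1 in both the NRF2 and the CAR and PXR lists. Ugt2b1 and Ugt1a1 are in both the CAR and PXR and the UDP-glucuronosyltransferase lists. Of 31 NRF2 target genes 4 rose and 0 fell (median 0.36), and 14 rose adjusted over the list alone (camera adjusted p = 4.56e-09, and adjusted p = 0.0687 with an estimated correlation). The 4 were Nqo1, Gstp1, a glutathione transferase (3.31-fold, 2.75 to 3.97, adjusted p = 0.00735), Srxn1, sulfiredoxin (3.24-fold), and Ephx1, microsomal epoxide hydrolase (2.00-fold). Of 21 glutathione transferases 2 rose, Gstp1 and Gstm2 (2.03-fold), and 6 did so over the list alone (median 0.21, adjusted p = 0.00117, and adjusted p = 0.36 with an estimated correlation). Gstm1 was 15.1-fold above corn oil with an interval of 4.93 to 46.1 and was not called (adjusted p = 0.0624), although it was called without corn oil replicate 1 (adjusted p = 0.0359) and under 3 more of 22 alternatives, over which adjusted p ranged from 0.00606 to 0.244. Hmox1, heme oxygenase, had a log2 fold change of 3.05 ± 1.61 and was not called (adjusted p = 0.39). Its level was 5.62 on monuron replicate 1, -0.22 on each other monuron array and between -1.57 and -1.09 on the corn oil arrays, and without monuron replicate 1 the log2 fold change was 1.1 ± 0.16 (adjusted p = 0.0984, 0.0984 to 0.693 over the alternatives).

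Of 15 CAR and PXR target genes, which respond to drugs and other foreign compounds, 3 rose (Abcc2, Abcb1b and Ephx1) and 8 rose adjusted over the list alone (median 0.68, camera adjusted p = 1.01e-05, and adjusted p = 0.0933 with an estimated correlation). Liver transcripts varied between arrays alongside this list: Alb lay at 2.67 on corn oil replicate 3 and 3.93 on monuron replicate 1, at 2.12 and 2.04 on monuron replicates 2 and 3, and at 0.41 and 0.12 on corn oil replicates 1 and 2. Of 5 AhR target genes Nqo1 alone rose, with 4 over the list alone (median 0.67, adjusted p = 0.00427, and adjusted p = 0.196 with an estimated correlation). Cyp1a2, also an abundant liver transcript, was not well above background with corn oil, at least 4.47-fold higher with monuron, and not called (adjusted p = 0.0763). Of 19 UDP-glucuronosyltransferase and sulfotransferase genes none was called over all genes, whereas 7 were higher and 1 lower adjusted over the list alone (median 0.52, adjusted p = 0.00527, and adjusted p = 0.196 with an estimated correlation). That list's call was lost without corn oil replicate 1 (median 0.32, adjusted p = 0.0686, the highest of the alternatives, the lowest being 2.56e-09). Ugt2b1 was at least 2.07-fold higher but not called (adjusted p = 0.1). Of 25 cholesterol synthesis genes 1 rose, the squalene epoxidase gene Sqle (1.63-fold), with 9 over the list alone (median 0.19, adjusted p = 3.78e-05, and adjusted p = 0.395 with an estimated correlation).

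**Figure D2:**
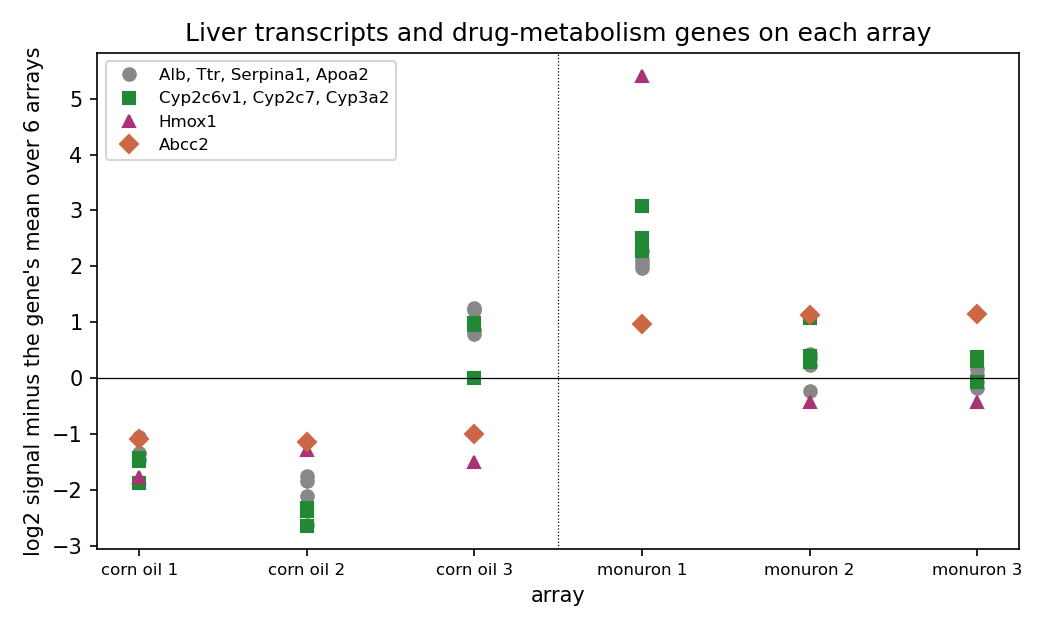
Level of liver transcripts, cytochrome P450 genes, Hmox1 and Abcc2 on each of the 6 arrays (x axis), as log2 signal minus the gene's mean over the arrays (y axis); points are single arrays. Alb, Ttr, Serpina1 and Apoa2 and the 3 cytochromes are highest on monuron replicate 1 and above their mean, or level with it for 1 cytochrome, on corn oil replicate 3, whereas Abcc2 lies apart in the 2 groups.

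Some metabolic and proximal tubule lists were called lower, by smaller amounts. Among 35 genes of fatty acid oxidation and PPAR alpha targets none was called over all genes and 14 were lower adjusted over the list alone (median -0.23, camera adjusted p = 5.86e-08, and adjusted p = 0.0933 with an estimated correlation). Cyp4a1, a fatty acid hydroxylase, had a log2 fold change of -0.49 ± 0.08 (adjusted p = 0.0586). Of 12 markers of proximal tubule segments S1 and S2, 11 had a log2 fold change below 0 and 0 were called, with 2 lower over the list alone (median -0.23, adjusted p = 3.78e-05, and adjusted p = 0.109 with an estimated correlation). The endocytic receptor genes Cubn and Lrp2 stood at -0.69 ± 0.12 and -0.52 ± 0.10, and the phosphate transporter gene Slc34a1 at -0.09 ± 0.10. Markers of segment S3 had a median of 0.17 (adjusted p = 0.938).

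Of 27 genes of nutrient and ion reabsorption in the proximal tubule none was called, and 1 was higher and 4 lower over the list alone (median -0.10, adjusted p = 0.00573, and adjusted p = 0.196 with an estimated correlation). This list shares 9 genes with the S1 and S2 list, so their calls are not independent. Of 37 amino acid degradation genes 1 fell, Dmgdh, dimethylglycine dehydrogenase (1.87-fold lower), with 2 over the list alone (median -0.05, adjusted p = 0.00966, and adjusted p = 0.206 with an estimated correlation). Of 11 gluconeogenesis genes 1 fell, the pyruvate carboxylase gene Pc (1.41-fold lower), also over the list alone (median -0.11, adjusted p = 0.0284, and adjusted p = 0.554 with an estimated correlation). Both calls depended on single arrays: without corn oil replicate 2 the amino acid list had a median of -0.03 and adjusted p = 0.0601 and the gluconeogenesis list a median of -0.05 and adjusted p = 0.279, and the latter also missed the threshold without corn oil replicate 3 (0.0633), monuron replicate 1 (0.0633) or monuron replicate 3 (0.0563). Over all alternatives the adjusted p ranged from 0.00148 to 0.134 for the amino acid list and from 0.00269 to 0.454 for the gluconeogenesis list. The gluconeogenesis list was called under 13 of 22 alternatives and missed the threshold under 9. Without a detection filter the reabsorption, amino acid and gluconeogenesis lists were not called.

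Some immune and other cell type lists were also called lower. Of 27 interferon response genes 2 fell, Usp18 and the transcription factor gene Irf7 (2.11-fold lower), and 8 over the list alone (median -0.30, adjusted p = 4.13e-05, and adjusted p = 0.336 with an estimated correlation). Ifit3 stood at -1.08 ± 0.17 (adjusted p = 0.0504). Macrophage markers (15 measured, median -0.26, adjusted p = 0.00168, and adjusted p = 0.554 with an estimated correlation) and T and NK cell markers (14 measured, median -0.35, adjusted p = 0.00177, and adjusted p = 0.395 with an estimated correlation) had 0 called members, with 0 and 1 lower over the list alone. Macrophage markers were highest on corn oil replicate 3, without which the list had a median of -0.12 and adjusted p = 0.0815 (7.98e-06 to 0.727 over the alternatives). Antigen presentation genes (14 measured, median -0.18, adjusted p = 0.0136, and adjusted p = 0.615 with an estimated correlation) lost their call without corn oil replicate 1 (median -0.03, adjusted p = 0.281) or monuron replicate 1 (median -0.06, adjusted p = 0.138), with a range of 1.52e-05 to 0.44 over the alternatives. Endothelial markers (13 measured, median -0.16, adjusted p = 0.00868, and adjusted p = 0.476 with an estimated correlation) lost it without corn oil replicate 3 (0.0558) or monuron replicate 3 (median -0.08, adjusted p = 0.0548), with a range of 0.000337 to 0.351. Podocyte markers (13 measured, median -0.13, adjusted p = 0.0321, and adjusted p = 0.481 with an estimated correlation) lost it without corn oil replicate 1 (0.11), corn oil replicate 2 (0.142), monuron replicate 2 (0.0556) or monuron replicate 3 (0.0548), with a range of 9.82e-05 to 0.21. Without a detection filter these 3 lists were not called, and without scaling the podocyte list was not. With the hepatocyte score as a covariate the medians were -0.03 for antigen presentation and -0.0061 for podocyte, not called. In these 3 lists 0 members were called, over all genes or over the list alone.

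**Figure D3:**
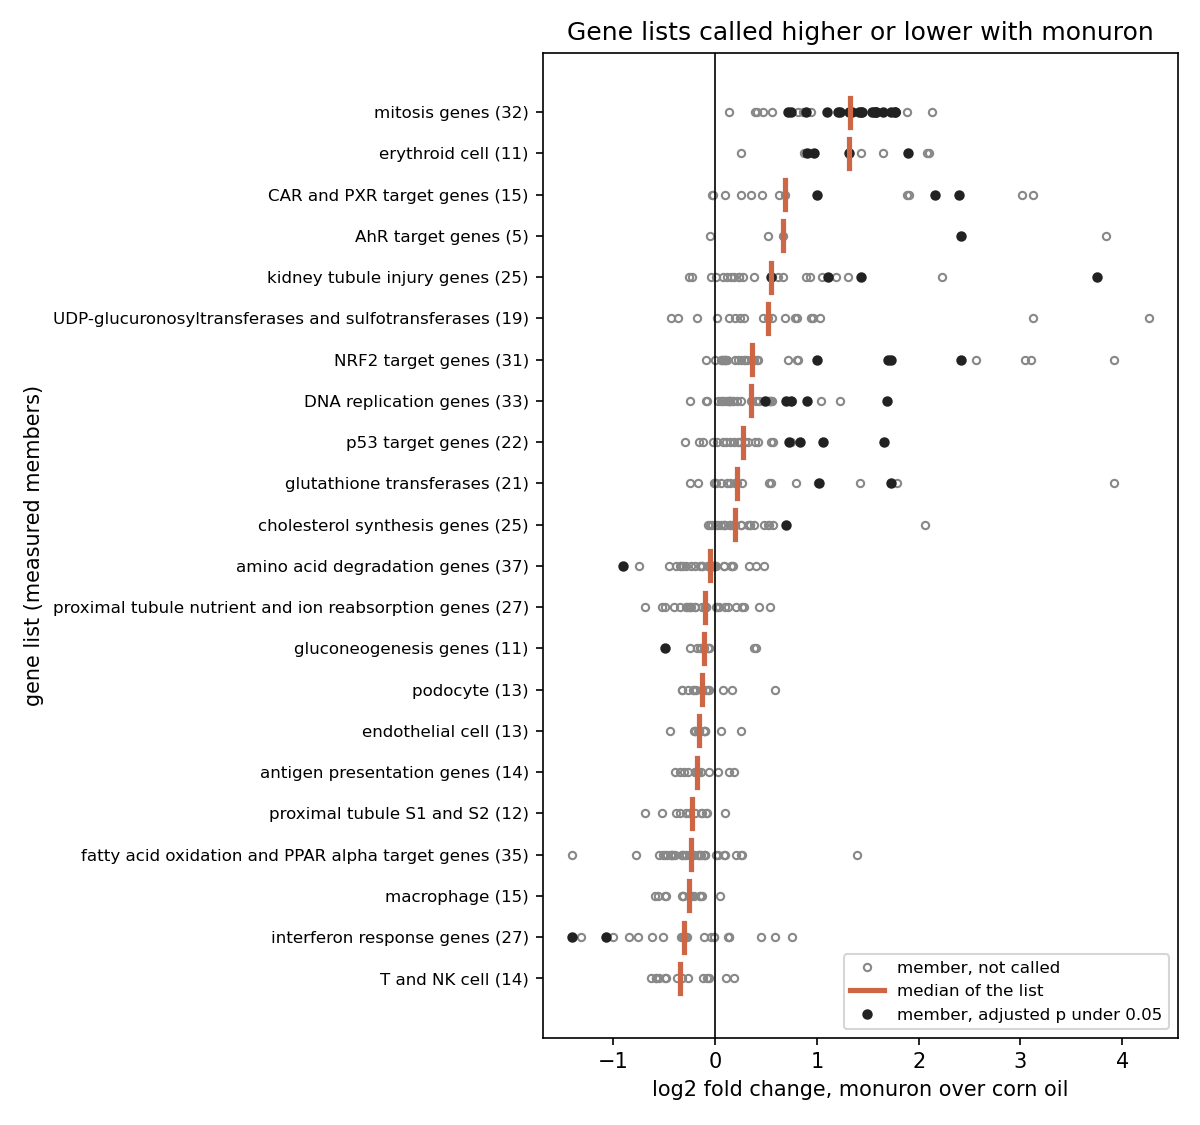
Log2 fold change, monuron over corn oil (x axis), of every measured member of the 22 lists called at the preset correlation (y axis, measured members in brackets); filled points are called members and the bar is the list's median. Mitosis genes lie highest with a median of 1.32, and the lower lists have medians between -0.35 and -0.05.

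The smallest adjusted p with the estimated correlation was 0.0687, and fry called 13 lists. Of the lists called at the preset correlation, fry did not call interferon response (adjusted p = 0.0540), glutathione transferases (0.0540) or cholesterol synthesis (0.0584). Nor did it call gluconeogenesis (0.189), T and NK cell (0.190), podocyte (0.207), endothelial (0.208), macrophage (0.337) or antigen presentation (0.405). The other 29 lists were not called with the preset correlation. Markers of other nephron parts and vessels had these median log2 fold changes: thick ascending limb -0.00, distal convoluted tubule -0.04, collecting duct principal cell -0.07, intercalated cell 0.10, medulla 0.13, mesangial and smooth muscle cell -0.02 and urothelium 0.21. Umod and Aqp2 lay at -0.00 ± 0.21 and 0.10 ± 0.21, and Kcne1 of the collecting duct list was 1.67-fold lower (adjusted p = 0.0324). Markers of further cell types had medians of -0.29 for adipocyte (adjusted p = 0.0507), 0.21 for neutrophil and mast cell, 0.58 for hepatocyte (0.55 with dim genes at their bound), 0.04 for fibroblast, 0.03 for B and plasma cell, 0.05 for adrenal cortex and 0.07 for skeletal muscle, of which the actin gene Acta1 was 1.94-fold higher (adjusted p = 0.019, well above background on 2 of 3 corn oil arrays). Some of these lists passed the threshold when an array was left out. The hepatocyte list was higher without corn oil replicate 3 (adjusted p = 0.00349, 2.45e-08 to 0.821 over the alternatives) and the neutrophil list without monuron replicate 1 (0.0194, 0.0189 to 0.443). The adipocyte list was lower without corn oil replicate 1 (0.0166, 0.0166 to 0.735) or monuron replicate 1 (0.0237), and the collecting duct principal cell list without corn oil replicate 3 (0.0433, 0.0184 to 0.892). Counting settings that kept every array, the adipocyte list was called under 5 of 22 alternatives. Stress and signalling lists had medians of 0.20 for immediate early genes, 0.06 for heat shock genes, 0.08 for the unfolded protein and integrated stress response, 0.12 for inflammatory cytokine and NF-kB genes, -0.09 for metallothionein and zinc genes, 0.10 for heme and iron handling and -0.04 for extracellular matrix. The medians were 0.11 for fatty acid synthesis, 0.08 for glycolysis and hypoxia, 0.01 for the mitochondrial respiratory chain, -0.08 for renin-angiotensin and mineralocorticoid genes (called lower without monuron replicate 2, adjusted p = 0.0247, 0.0247 to 0.576 over the alternatives), -0.10 for circadian clock genes, 0.03 for vitamin D, calcium and phosphate genes and -0.02 for proximal tubule drug transporters, of which Abcc2 and Abcb1b rose. With spike-in scaling the drug transporter median was -0.52 and the list was called higher relative to other genes (adjusted p = 0.00859, the lowest over the alternatives, the highest being 1.00). Median, mean and test differed in sign for fibroblast, respiratory chain, distal convoluted tubule, circadian clock, vitamin D, drug transporter and B cell lists.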

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

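Both tests below were chosen after the spike-in values had been seen. The adenovirus E1A spike-in transcripts, which are added to the labelling reaction and belong to no comparison above, gave a higher signal relative to the array's 75th percentile on the monuron arrays than on the corn oil controls. The difference over the 7 detected spike-in probes averaged 0.50 on the log2 scale, and each probe was higher on all 3 monuron arrays. An exact two-sided permutation test gives 0.1, the smallest p that 3 against 3 arrays allow. The differences were 0.28 for E1A_r60_1, 0.63 for E1A_r60_a135, 0.47 for E1A_r60_a20, 0.66 for E1A_r60_a22, 0.50 for E1A_r60_a97, 0.54 for E1A_r60_n11 and 0.45 for E1A_r60_n9.

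Brighter scanning of the monuron slide is argued against as the sole cause. Scaled values cannot test it, but without scaling the spike-ins differed by 0.37 to 0.74 and rat probes within 0.25 of their log2 levels by a median of at most 0.097. More spike-in, or less rat messenger RNA, in the monuron labelling reactions stays open: all probes moved the same way, but with an SD of 0.12 between them, and labelling and treatment share the slides. A lower messenger RNA content of the dosed cortex is a biological reading that was not tested.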

How the results depend on the processing

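The spike-in scaling, the removal of 2 arrays together and the liver covariate were chosen after seeing the data. All 412 called genes kept their sign under each of the 19 alternatives fixed beforehand except the floor on low values, where 410 did, and detection on all 6 arrays, where 343 did and the rest were not tested. For some alternatives this was fixed in advance. The groups of all 412 did not overlap, so leaving out 1 array could not turn the sign of a probe. Array weights, the replicate block and eBayes with trend and robust refitted the same values and could not turn it either. Every probe on its own was judged on the probe of the main fit, with the same values, so that sign was fixed too. Detection on all 6 arrays reuses those values, and the authors' table holds them up to scaling and rounding, so their kept signs add little. Quantile normalization, median centring, the authors' table, detection on all 6 arrays, the floor, the mean of a gene's probes, every probe on its own and array weights kept every count within 1.5 times. Normexp called 449 genes higher and 320 lower (58.4% higher against 69.7%), and eBayes with trend and robust 431 and 276; the cause was not tested. No scaling gave 366 higher and 61 lower (85.7% higher), with the median of all genes at 0.11; the cause was not tested. Without a detection filter 45433 genes were tested, and 67 were higher and 19 lower. Of these 64 and 16 differed at least 2-fold, and 5 lists were lower. More genes were tested there than in the main fit, but the cause of the fall in calls was not tested.

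Leaving out each array gave 25 to 1.1e+02 (rounded to 2 digits) genes higher and 5 to 27 lower, 25 to 99 and 5 to 18 at least 2-fold, 10 to 12 lists higher and 8 to 11 lower, with fewer arrays in each fit. Of 53 called named genes, Havcr1, Ckap2, Abcc2, Gstp1 and Ccnb2 kept their call each time, as did 15 of 22 called lists. Without corn oil replicate 3 and monuron replicate 1 together, which leaves 4 arrays, limma called 0 genes higher and 0 lower. It called 0 at least 2-fold either way, with 4190 genes at an unadjusted p under 0.05. All 412 called genes kept their sign there, which was fixed in advance for a probe because the groups did not overlap. Log2 fold changes with and without the pair were 3.75 and 3.93 for Havcr1, 2.26 and 2.23 for Ckap2, and 2.17 and 2.26 for Abcc2. Gabbr2 moved more, from -2.77 to -2.42. With the hepatocyte score as a covariate 96 genes were higher and 16 lower, 88 and 13 at least 2-fold; the cause was not tested.

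With the replicate number as a block limma called 0 genes higher and 0 lower, 0 at least 2-fold, with 4557 at an unadjusted p under 0.05. The block takes residual degrees of freedom from a fit of 6 arrays. For example, Abcc2 stood at 2.17 ± 0.08 with and without the block, but was not called with it (adjusted p = 0.0598). How much of the loss this accounts for was not tested. The values gave no sign that the replicate numbers pair the samples. Deviations from the group mean correlated across genes between same-numbered arrays at -0.08, 0.11 and -0.17, and not every array correlated best with its own number. Arrays of different numbers correlated at -0.13 to 0.22. Deviations within a group of 3 sum to 0, so these correlations are tied together and cannot exclude a pairing.

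Spike-in scaling moved the median of all genes to -0.48 and called 20640 genes lower, 728 at least 2-fold, and 303 higher (1.45% higher), with 20 lists higher and 4 lower. It shifted every gene by about -0.50, so 17 of the 412 called genes changed sign and 5 of the 11 lists called higher had medians below 0. Among the named genes and lists whose direction turned with a call on either side, it brought Cdkn1a to -0.35 and Cdc45 to -0.010, and proximal tubule drug transporters, at a median of -0.52, from lower to higher relative to other genes. The cause was not tested. Of uncalled named values 91 changed sign without a call. Signal over background limited 13 values of named genes and lists that detection on all 6 arrays left out. A slide block could not be run.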

Other observations

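The tests of the C_CA probes and of the cell division and liver transcript patterns were chosen after those results had been seen, and the count of splits was fixed beforehand. The array carries 676 probes with the prefix C_CA, which the files pair with no gene. Of the 641 tested, 34 were called when every probe was tested on its own, 24 higher and 10 lower, or 5.30%. Of the 40484 other probes 1.16% were called (Fisher's exact test, two-sided, p = 1.29e-12, over probes, which are not independent). The probe sets were not matched on signal level. Of the C_CA probes 641 of 676 passed the detection filter, against 41125 of all 61537 non-control probes. The test therefore cannot separate a stronger response of the C_CA probes from easier detection of change.

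Of the 10 splits of the 6 arrays into 3 and 3, the real split gave 287 genes higher and 125 lower, 150 and 41 at least 2-fold, where the highest other split gave 2 genes on a side and 1 of the 10 splits, the real one, reached each count. For lists, the real split gave 11 higher and 11 lower, and 2 of the 10 splits gave as many, the highest other being 13. That split set corn oil replicates 1 and 2 with monuron replicate 1 against the rest. Every other split also called lists, from 2 to 13 in one direction and from 0 to 7 in the other. At the preset correlation, lists were thus called even where each side held arrays of both groups. With 10 splits no share under 0.05 can be reached. Every other split also mixes the groups on each side. A difference between groups or slides then widens the spread within the sides, so few called genes there were fixed by the design. Part of such a difference stays between the sides, so lists called there do not measure false calls.

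Mitosis and DNA replication genes were higher with monuron as lists at the preset correlation, with 19 of 32 and 5 of 33 called, but not with an estimated correlation (adjusted p = 0.0954 and 0.0687). A signal-dependent shift between the slides is argued against as the cause: of 10000 random lists matched on mean level, 0 reached the median of either list, the highest being 0.19 and 0.20. Dividing erythroid precursors in the tissue may contribute, since the erythroid cell list had a median of 1.31; the mean mitosis level was higher on monuron replicate 2 than 3 (0.71 and 0.53) and the erythroid level lower (0.49 and 0.85), but 3 arrays are too few to decide. Slide, labelling or scan day cannot be told apart from treatment, with 0 slides holding both groups, and an effect of monuron on kidney cell division stays open.

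The CAR and PXR list is a mixture. Cyp2c6v1, Cyp2c7 and Cyp3a2, named after their values were seen, followed the mean level of 12 hepatocyte markers (Fgb, 1 of them, is also in the tubule injury list) over the arrays (slopes of 1.76 to 2.00). By the same test no slope was called for Cyp2b2 (0.27) or Cyp2c11 (0.03). Cyp2c11 was too variable to decide, with a log2 fold change of 0.23 ± 1.40 beside the score. Alb lay above 2 on all 3 monuron arrays and corn oil replicate 3. With the hepatocyte score in the model, the median log2 fold change of the 5 cytochrome P450 members went from 1.89 to 0.42, consistent with liver RNA in some of the samples as a candidate source, while Cyp2c6v1 went from 3.02 to 1.68 ± 0.24. The 10 other members went from 0.57 to 0.59, and 7 kept an interval above 0, Abcc2 at 2.17 ± 0.10. This argues against liver RNA of the same make-up in both groups as the cause of those rises. The score cannot account for liver transcripts that themselves differ between the groups, so liver RNA is not excluded. Ugt2b1, 1 of the 7, lay at -2.97 on monuron replicate 1, where Alb was highest, and at -4.83 and -5.29 on monuron replicates 2 and 3. Slide and treatment stay open for both parts.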
